A study of Mus musculus with 6 samples.

How the data were processed

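The series profiled single cells from mice labelled wild type or KO for Zfp683, the gene that encodes the transcription factor Hobit. Lymphocytes came from 3 tissues, the liver, the salivary gland and the small intestinal lamina propria, with 1 library per genotype and tissue. Per the labels' protocols, the intestine was stripped with EDTA and digested with collagenase, the cells were enriched on a density gradient, and libraries were made with the 10x Genomics Chromium 3′ kit, which tags the 3′ end of each captured RNA with a cell barcode and a unique molecular identifier (UMI). The labels name innate lymphoid cells and natural killer (NK) cells but give no sort gate.

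The values used were raw UMI counts per gene and cell barcode in the matrices the authors deposited, which Cell Ranger 6.0.1 wrote, per the file headers. The mouse genome build mm10, Cell Ranger and Seurat are named per the submitters' processing notes, with no roles given. Whether barcodes were filtered beyond cell calling is not given in the sources used here. The lowest UMI total of a barcode was 500 in WT_LP and 501 in KO_LP. Gene counts were analysed for the wild-type and KO lamina propria libraries (WT_LP and KO_LP). Gene counts of the liver and salivary gland libraries were not analysed here, and only their barcodes were counted. Any library pair shared between 4 and 22 barcodes. The files list 32285 gene IDs, of which 32158 are in GENCODE M21 on GRCm38 (mm10), which gave the coordinates.

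Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Of 5518 barcodes in WT_LP and 3747 in KO_LP, 5122 and 3455 passed. Scrublet then marked 2 and 5 cells as doublets, and these were removed. That is under 0.5% of the cells, so doublet calling did not work here. Removing the 5% of cells with the highest doublet scores was therefore added as an alternative after the data were seen. The analysis kept 5120 cells with 29075669 UMIs in WT_LP and 3450 cells with 22393679 UMIs in KO_LP.

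Both libraries were clustered together with scanpy 1.11.5 in Python 3.11.15, without batch correction. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, ranked with the library as batch, entered 30 principal components and a graph of 15 nearest neighbours. Leiden community detection (leidenalg 0.10.2) at resolution 1 gave 20 clusters, numbered from 0. Mitochondrial, ribosomal protein, immunoglobulin, haemoglobin and T cell receptor genes and Zfp683 itself were left out of the variable genes. A cluster was called "X-like" from marker lists of 13 cell types fixed before the data were examined. The thresholds for a name were set after the data were seen: a mean log2 fold of the markers of at least 0.25, at least 3 markers at 1.5 times or more, no other class with more markers among the 10 leading genes, and a median depth of at least 1/3 of the library's. Folds for this purpose had 10 CPM added to each side. Clusters 0, 2, 3, 10 and 11 stayed unnamed and held 51.8% of the WT_LP cells and 38.6% of the KO_LP cells.

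UMIs were summed per library and cell group and expressed as CPM (counts per 1e6 UMIs of the group). Gene counts were analysed for 1 tissue only, with 1 library per genotype, so no test was possible on them and no p-value is given. Log2 ratios of CPM (KO_LP over WT_LP) carry 95% exact conditional binomial intervals, CPM carry exact Poisson intervals, and shares of cells carry exact Clopper-Pearson intervals. The interval of a difference of shares combines the bounds of both shares by the square root of their summed squares. All intervals cover counting error only, not the difference between animals or captures or the uneven spread of a gene's UMIs over cells. Groups needed at least 50 cells in each library. Plain CPM was the main scaling. TMM factors (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0, in R 4.3.3) served as alternatives. They shifted the log2 ratios in clusters 1 and 2 by -0.04 and -0.05.

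For each of 16 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 10 UMIs in both libraries together, with 0.5 counts added. Its interval comes from 1000 Poisson resamples. Its percentile among 10000 random lists of equal size and similar expression describes these libraries and is not a test. For shares of cells with a UMI of a gene, each cell was thinned to a fixed number of UMIs and shallower cells were left out.

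The genes named in the text were Zfp683, list members with the largest ratio by the interval bound nearest 0, and the 10 genes with the largest difference each way by the same bound, among genes at 50 CPM or more in at least 1 library and with 30 UMIs or more over both. Several choices were made after the data were seen. Clusters 1 and 2 were summed, and other groups were compared by cluster number. Genes among the 10 that define a cluster were left out of the named genes of that cluster, though they stayed in the list medians. In clusters 3, 4 and 6 only the leading 3 genes each way are given, 2 examples were given per list, and outside clusters 1 and 2 only some lists are given. Cluster 4 stood in for all T-like cells, and cluster 5 alone was used for Gzmb in NK-like cells because Gzmb helps to define cluster 12. Ncr1 is given in every group because it carries the Cre driver, which was also decided after its values were seen.

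The intervals and list percentiles were tested on simulated data with 200 changed genes. The interval held the true ratio for 95.8% of genes simulated for clusters 1 and 2, 95.9% for NK-like cells and 95.8% for cluster 0. In clusters 1 and 2 the interval lay on the true side of 0 for 71.2% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 98.5% of those changed by 2. The simulated sums carried only the counting error that the intervals assume, so this coverage cannot check the intervals on real cells. There a gene's UMIs can come from few cells, as for S100g in cluster 6 of KO_LP (52 UMIs from 2 cells). Intervals of such genes can be too narrow. Alternatives tried were no cell filter and a stricter filter (1000 genes, 2000 UMIs, 5% mitochondrial), doublet calls kept, Leiden resolutions 0.5 and 2, clustering without the members of 5 outcome lists, clustering without genes over 2 times apart between the libraries, each library clustered alone, the whole library in place of a group, means over cells in place of sums, list minimums of 50 UMIs and 1 UMI, and another thinning depth. Cluster 1 alone, cluster 2 alone, cluster 5 alone, shares of the cells outside cluster 0 and cells with few heat-shock UMIs were added after the data were seen.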

Results

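Single-cell RNA sequencing was applied to lymphocytes from mice labelled wild type (WT) or Hobit KO. Hobit, the product of Zfp683, is a zinc-finger transcription factor related to Blimp-1 (Prdm1) and linked to tissue-resident lymphocytes. Type 1 innate lymphoid cells (ILC1s) are tissue-resident producers of interferon gamma that are related to circulating natural killer (NK) cells. The KO mice carried Zfp683 alleles flanked by loxP sites (flox) and a Cre recombinase under the control of Ncr1, the gene of the activating receptor NKp46 found on ILC1s, NK cells and part of the group 3 innate lymphoid cells (ILC3s). All mice were 8 weeks old C57BL/6J animals, and the 6 libraries comprised 1 per genotype from liver, salivary gland and small intestinal lamina propria, the connective tissue under the gut epithelium. The liver libraries held 12242 (WT) and 7337 (KO) cell barcodes and the salivary gland libraries held 3785 (WT) and 4814 (KO). The comparison of gene counts concerned the lamina propria, where the WT library (WT_LP) held 29622652 UMIs and the KO library (KO_LP) 23098308. The kept cells had a median of 4950 UMIs and 1794 genes in WT_LP (5120 cells) and of 5407 UMIs and 1870 genes in KO_LP (3450 cells). With no replicate library, every difference given here is a difference between these 2 libraries and has no replicate check.

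Zfp683, the targeted gene, was not lower in the library labelled KO. In the ILC1-like cluster 1 and the unnamed cluster 2, which together held most Zfp683 transcripts, 51 UMIs were counted in WT_LP and 52 in KO_LP, or 7.50 CPM (95% interval 5.59 to 9.86) and 7.92 CPM (5.91 to 10.4), with a log2 ratio of 0.08 (-0.51 to 0.66). Over all kept cells the sums were 80 and 77 UMIs (2.75 and 3.44 CPM). NK-like cells had 1 and 2 UMIs, cluster 0 had 4 and 1, cluster 3 had 7 and 3, the T-like cluster 4 had 7 and 11, and cluster 6 had 0 in both libraries (upper bounds 4.05 and 5.97 CPM). Zfp683 lies on chromosome 4 from 134053838 to 134058996 on the plus strand (GRCm38, GENCODE M21, protein-coding). The assay counts 3′ ends and the labels do not say which exons were floxed, so 3′ tags outside the deleted part check nothing. In what follows KO_LP is the library labelled KO, whatever its state of deletion.

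The lamina propria cells formed 20 clusters of innate lymphoid cells, T cells and smaller populations. Cluster 0 took 27.7% of the WT_LP cells (1417 cells, 95% interval 26.5 to 28.9) and 12.2% of the KO_LP cells (422 cells, 11.2 to 13.4), a difference of -15.4 percentage points (-17.1 to -13.8). It stayed unnamed because Arg1, a marker of group 2 cells, stood among its leading genes (Pram1, Upp1 and Hs6st2 first) and no ILC3 marker did. The ILC1-like cluster 1, led by Ccl4, Gzmc and Ifitm2, and the unnamed cluster 2, led by Areg, Acod1 and Nr4a3, together took 25.9% (24.7 to 27.1) in WT_LP and 35.3% (33.7 to 36.9) in KO_LP, a difference of 9.38 points (7.37 to 11.4). T-like cells made up 14.1% and 18.7%, a difference of 4.64 points (3.02 to 6.28). Shares sum to 100%, and among the cells outside cluster 0 the difference was 4.38 points (2.03 to 6.73) for clusters 1 and 2, 1.86 points (-0.091 to 3.83, which holds 0) for T-like cells and -0.67 points for NK-like cells, with 0 inside its interval as well. Smaller differences separated NK-like cells (clusters 5 and 12, 9.92% and 11.4%), cluster 3 (unnamed, 10.9% and 9.42%) and the ILC3-like cluster 6 (3.59% and 3.04%). The interval of the cluster 6 difference held 0 (-1.32 to 0.249 points), and the cluster 3 difference turned to 0.605 points with no cell filter. Clustering without genes over 2 times apart between the libraries gave differences of -15.2 points for cluster 0 and 9.76 points for clusters 1 and 2. These are shares of sequenced cells: the sort gate, which the labels do not give, can set them, and the median depth was higher in KO_LP. Of cluster 0 most cells came from WT_LP, so it may hold features of that library as well as of a cell type.

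**Figure D1:**
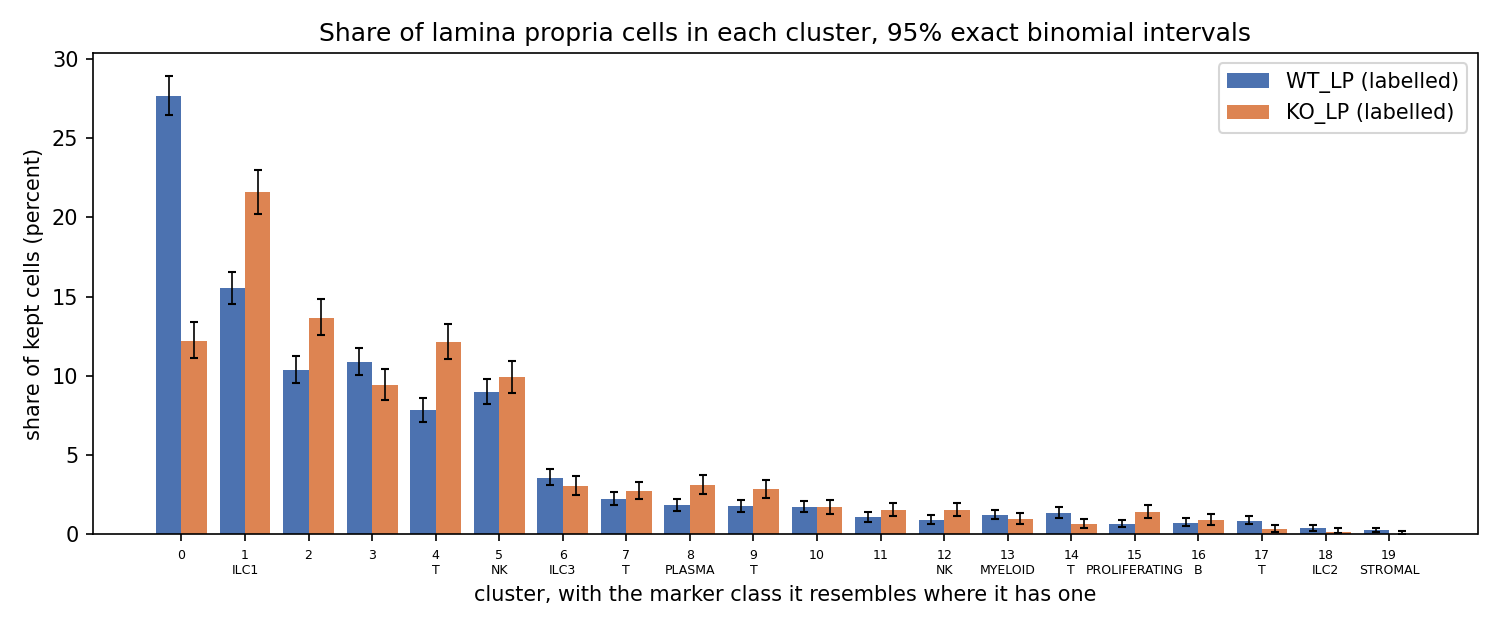
Share of the kept lamina propria cells (percent, vertical axis) in each of 20 clusters (horizontal axis) in the libraries labelled WT_LP (blue) and KO_LP (orange), with 95% exact binomial intervals that cover counting error only. Cluster 0 stands at 27.7% in WT_LP and 12.2% in KO_LP, and cluster 1 at 15.5% and 21.6%.

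The ILC1-like cluster 1 and the unnamed cluster 2 (together 1326 cells in WT_LP and 1217 in KO_LP) had less effector transcript in the library labelled KO. Gzmb, a granule protease that triggers death of target cells, stood at 273.9 CPM in WT_LP and 102.9 CPM in KO_LP (log2 ratio -1.41, -1.54 to -1.28). Tnfsf9, the ligand of the costimulatory receptor 4-1BB, had 55.6 and 19.6 CPM (-1.50, -1.80 to -1.21), and Csf2, the growth factor GM-CSF, had 120.5 and 52.8 CPM (-1.19, -1.38 to -1.01). The reverse held for Tcf7, which encodes TCF1, a transcription factor of naive and progenitor lymphocytes, with 92.1 CPM in WT_LP and 151 CPM in KO_LP (0.72, 0.57 to 0.86). Gzmb lies on chromosome 14 from 56258838 to 56262260 (minus strand) and Tcf7 on chromosome 11 from 52252371 to 52283014 (minus strand), both protein-coding in GRCm38.

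Among other genes lower in KO_LP in clusters 1 and 2, Ncr1 had 727 and 367 CPM (log2 ratio -0.99, -1.06 to -0.92). The stress-inducible Gadd45g stood at 115.8 and 54.2 CPM (-1.09), the protease inhibitor gene Ctla2a at 872 and 473 UMIs (-0.83) and the survival kinase gene Pim2 at 196 and 120.9 CPM (-0.70). Among genes higher in KO_LP, Cxcl2, a neutrophil chemokine, had 30.9 and 79.0 CPM (1.36), from 39 cells in WT_LP and 44 cells in KO_LP. Cdkn1a, the cell-cycle inhibitor p21, had 113.7 and 223 CPM (0.97), Ccr9, the gut-homing chemokine receptor, 82.2 and 149 CPM (0.86), and the arrestin-domain gene Arrdc3 58.4 and 109.6 CPM (0.91). Heat-shock chaperones made up much of the rest: Hspa1b (0.90), Hspa1a (0.89), Dnajb1 (0.88), Hsph1 (0.86) and Hsp90aa1 (0.66), and the predicted gene Gm42031 stood at 1.24. Hspa1a, Hspa1b, Dnajb1 and Hsph1 together took 1549 CPM of these clusters in WT_LP and 2871 CPM in KO_LP. In cells with little heat-shock RNA, an alternative added after the data were seen, Hspa1b had a ratio of -0.08 and Gzmb of -1.28. The change in Hspa1b is no check, because the cells were chosen by these heat-shock genes. Jchain, a plasma cell gene that can reach other cells as free RNA, was lower in KO_LP as well (110.6 and 47.7 CPM, -1.21), while erythroid markers were higher (3.97 and 12.0 CPM). Over all kept cells Jchain was higher in KO_LP (5168 and 7648 CPM), and free RNA was not measured.

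Several fixed gene lists differed in clusters 1 and 2 as well. Of the cytotoxic granule genes, 14 of 17 measured members had a lower and 3 a higher CPM in KO_LP, with a median log2 ratio of -0.17 (-0.25 to -0.10), below all 10000 matched random lists. Besides Gzmb they included Nkg7, a granule membrane protein (1611 and 1161 CPM, -0.47). Type 1 cytokines and chemokines were lower for 10 of 13 members (median -0.27, -0.34 to -0.24, percentile 0.01), with Csf2 and the low-count Csf1, a macrophage growth factor (19 and 5 UMIs, -1.88), as examples. TCF1 program genes were higher for 9 of 14 members (median 0.21, 0.01 to 0.28, percentile 99.0), led by Tcf7 and the interleukin-7 receptor gene Il7r (527 and 641 CPM, 0.28), but the interval of this median reached 0 under TMM (-0.03 to 0.24) and median-of-ratios scaling (-0.03 to 0.23) and when the clusters were built without the outcome lists (-0.0043 to 0.26). NK receptor genes were lower for 17 of 25 (median -0.09, percentile 0.76), including Ncr1 and the low-count Ly49 receptor genes Klra8 (29 and 5 UMIs, -2.49) and Klra9 (75 and 22 UMIs, -1.72). Summed NK markers were lower too (-0.28). Immediate early and heat-shock genes were higher for 14 of 19 (median 0.09, percentile 99.3). That median turned to -0.053 in cells with little heat-shock RNA, which were chosen by members of this list. Survival and apoptosis genes were lower for 8 of 12 (median -0.09, percentile 2.47), with the anti-apoptotic Bcl2a1b at -0.46 and the pro-apoptotic Bcl2l11 (Bim) at 0.34.

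The remaining lists lay within the middle 95% of random lists in the sum of clusters 1 and 2. Tissue egress genes had a median of -0.08 (4 of 11 higher; Ly6c2 -0.88, Itgb1 -0.22) and tissue retention genes one of 0.05 (9 of 16 higher; Ccr9 0.86 and the lipid receptor gene Gpr55 0.80). For transcription factors of type 1 cells the median was 0.07 (14 of 20 higher), with Prdm1, which encodes Blimp-1, at 41.2 and 63.9 CPM (0.63) and the Ikaros-family gene Ikzf3 at 120 and 170.2 CPM (0.51). TGF-beta imprint genes had a median of 0.15 (11 of 14 higher) but a mean of -0.03, with the low-count Rgs16 at 11 and 1 UMIs while Skil, a repressor of SMAD signalling, stood at 0.44. In cluster 2 alone that median was 0.34 (0.22 to 0.45, 12 of 13 higher, percentile 99.99), in cluster 1 alone 0.09, and in cells with little heat-shock RNA 0.31. Cytokine receptor genes had a median near 0 (-0.04, Il23r -1.95 on 16 and 4 UMIs). So did genes of inhibitory receptors and intracellular regulators (-0.03, the receptor gene Lag3 -0.27, the transcription factor gene Nr4a2 0.20). Interferon response genes (-0.02, Oasl2 0.53, Bst2 0.09) and proliferation genes (-0.03, H2afz -0.14, Cdk1 0.27) lay near 0 as well. The ILC3 module had a median of 0.00 and a mean of -0.22, with Il22 at 41 and 18 UMIs. Only 2 targets of the aryl hydrocarbon receptor were measured, Tiparp at 337 and 517 CPM (0.62) and Ahrr at -0.06, too few for a median.

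**Figure D2:**
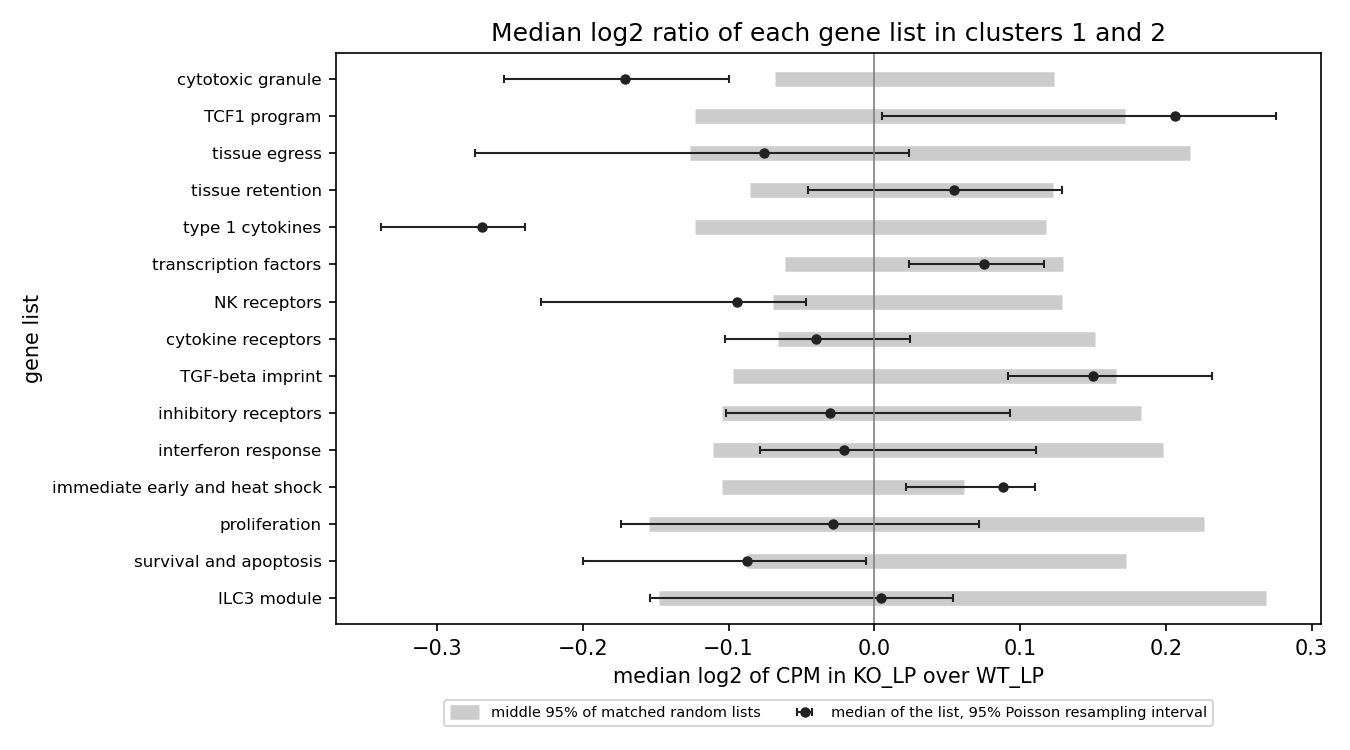
Median log2 ratio of CPM in KO_LP over WT_LP (horizontal axis) for 15 gene lists (vertical axis) in clusters 1 and 2, with 95% Poisson resampling intervals (black) and the middle 95% of matched random lists (grey bars). Cytotoxic granule genes (-0.17) and type 1 cytokines (-0.27) lie left of the grey bars, and TCF1 program genes (0.21) lie right of theirs.

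At a fixed 2900 UMIs per cell, Gzmb was detected in 18.3% of the cells of clusters 1 and 2 in WT_LP (16.2 to 20.6) and 9.56% in KO_LP (7.91 to 11.4), and Tcf7 in 22.2% (19.8 to 24.6) and 32.1% (29.4 to 34.9). Ifng, the interferon gamma gene, was detected in 58.7% and 49.6%, Prf1, the pore-forming perforin, in 30.6% and 25.4%, and the residency-linked chemokine receptor gene Cxcr6 in 46.1% and 38.8%. Gzma was detected in 20.2% and 19.3%, Il7r in 66.0% and 69.2%, Itga1, the integrin CD49a, in 13.6% and 13.7%, and Zfp683 in 2.26% and 2.39%. Eomes (0.921% and 0.619%) and Itgae (0.753% and 0.354%) were detected in few cells. Thinning left out 131 cells of WT_LP and 87 of KO_LP; unthinned shares were 23.0% and 12.5% for Gzmb and 33.1% and 48.8% for Tcf7, at median depths of 4782 and 4992 UMIs. In cluster 0, whose Gzmb level is low, the thinned Gzmb share was 3.28% in WT_LP and 2.05% in KO_LP at 3200 UMIs per cell. Unthinned median depths there were 4652 and 5035 UMIs. The Gzmb shares in clusters 1 and 2 lay above this low level, whose source was not measured.

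NK-like cells (508 in WT_LP and 395 in KO_LP, in clusters 5 and 12) had more transcript of genes of migrating cells in KO_LP. Klf2, a transcription factor that promotes recirculation, had 223 CPM in WT_LP and 342 CPM in KO_LP (log2 ratio 0.62, 0.48 to 0.75). Itga4, an integrin subunit of migrating lymphocytes, had 345 and 478 CPM (0.47). Prdm1, which is not among the tissue egress genes, was higher as well (31.1 and 53.7 CPM, 0.79). Lower in KO_LP were the adhesion molecule gene Jaml (91.1 and 33.3 CPM, -1.45), the growth factor receptor gene Kit (173.6 and 109.5 CPM, -0.67) and Ncr1 (563 and 357 CPM, -0.66). In cluster 5, which holds most NK-like cells, Gzmb had 581 CPM in WT_LP and 789 CPM in KO_LP (0.44, 0.35 to 0.53), opposite to clusters 1 and 2; that contrast was not tested. The small cluster 12, which Gzmb helps to define, had 3277 and 2298 CPM, and both NK-like clusters summed had a ratio of 0.28 (0.20 to 0.36).

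Tissue egress genes in NK-like cells had a higher CPM in KO_LP for 11 of 14 members (median log2 ratio 0.35, 0.12 to 0.48, above all 10000 random lists). Retention genes were lower for 12 of 16 (median -0.17, -0.26 to -0.11, percentile 0.39), with Gpr55 (54 and 12 UMIs) and the integrin gene Itgae (44 and 12 UMIs) as low-count examples. TCF1 program genes had a median of 0.23 (10 of 14 higher, percentile 99.9) but a mean of 0.06. The interval of 4 members lay above 0 and that of 4 below, and Kit and Il7r (37.5 and 21.1 CPM, -0.83) were lower. Granule genes had a median of -0.03 (8 of 19 higher, with Fasl at -0.36 and Lamp1 at -0.36). Prf1, which helps to define cluster 12, was higher in KO_LP in cluster 5 (229.8 and 303.6 CPM) and lower in cluster 12 (1804 and 1449 CPM). Further genes lower in KO_LP were Cd3g (-0.99), S100a4 (62.7 and 31.3 CPM), Gadd45b (-0.65), Ech1 (-0.69), Bcl2a1b (-0.58), Fos (-0.44) and the plasma cell gene Jchain (-1.17). Genes higher in KO_LP were the interferon-induced chemokine gene Cxcl10 (1.12), Hsph1 (0.96), the predicted genes Gm42031 (21.6 and 60.8 CPM), Gm43305 (1.20) and Gm47283 (1.01), and Lars2 (0.62) and Gm42418 (0.48), which often carry mitochondrial or ribosomal RNA reads. Markers of other cell types were lower in KO_LP in NK-like cells too: ILC1 markers (5717 and 4983 CPM, -0.20), ILC3 markers (251 and 154 CPM, -0.70) and T cell markers (1193 and 1041 CPM, -0.20). The egress median was 0.24 in cluster 5 alone and 0.10 in NK-like cells with little heat-shock RNA, where its interval (-0.10 to 0.41) held 0.

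In cluster 0 (1417 and 422 cells), the library labelled KO had a lower CPM of several cytokine and chemokine genes. Cxcl2 stood at 127 CPM in WT_LP and 50.4 CPM in KO_LP (log2 ratio -1.34, -1.64 to -1.05), Ccl5, a T cell chemokine, at 77.3 and 39.3 CPM (-0.97), Il22, an epithelial barrier cytokine, at 481 and 344 CPM (-0.48) and Xcl1, a chemokine for cross-presenting dendritic cells, at 526 and 384.5 CPM (-0.45). Ncr1 had 513 and 314 CPM (-0.71, -0.83 to -0.59). Ifng went the other way, with 377 and 433 CPM (0.20, 0.09 to 0.31). Type 1 cytokine genes had a median of -0.11 (7 of 11 lower, percentile 1.49), with the interval of 4 members below 0 and of 3 above, and NK receptor genes one of -0.13 (17 of 23 lower, percentile 0.38), with Ncr1 and the inhibitory receptor gene Klrc1 (86.0 and 58.3 CPM, -0.56) as examples. The ILC3 module had a median of -0.08 (7 of 11 lower, percentile 13.5), with Il22 and the interleukin-1 receptor gene Il1r1 (59.6 and 39.3 CPM, -0.60) in front. Summed ILC1 markers (-0.09), ILC3 markers (-0.12), myeloid markers (-0.16) and plasma cell markers (-0.84) were lower in KO_LP in cluster 0, and erythroid markers (3.65 and 11.1 CPM) were higher. Other genes lower in KO_LP were S100a6 (-0.62), Ptgs2 (-0.60) and Jchain (-1.23). Higher in KO_LP were the monocyte chemokine receptor gene Ccr2 (30.5 and 52.3 CPM, 0.78), Osgin1 (0.71), Rasa3 (0.63), Cdkn1a (0.55), Klf2 (112 and 159 CPM, 0.50), the stress-induced Atf3 (0.50), Adgrg5 (0.50), Rgs2 (0.49), Lars2 (0.58) and Gm42418 (0.42).

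**Figure D3:**
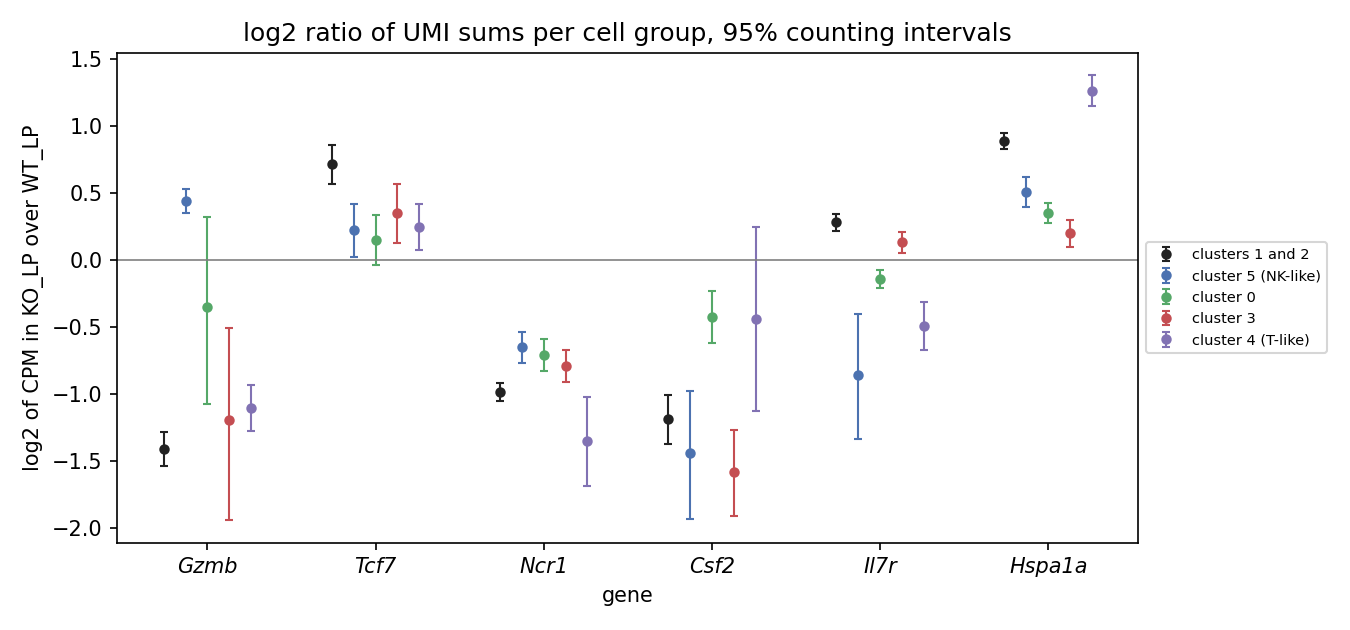
Log2 ratio of CPM in KO_LP over WT_LP (vertical axis) of 6 genes (horizontal axis) in 5 cell groups (colours), with 95% counting intervals. Gzmb lies at -1.41 in clusters 1 and 2 and at 0.44 in the NK-like cluster 5, while Ncr1 lies below 0 in each of the groups drawn.

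The unnamed cluster 3 and the ILC3-like cluster 6 both had a lower Csf2 in KO_LP. In cluster 3 (558 and 325 cells) Csf2 had 160.3 CPM in WT_LP and 53.6 CPM in KO_LP (log2 ratio -1.58, -1.91 to -1.27), Il22 184 and 61.2 CPM (-1.59, from 40 and 10 cells with a UMI) and Gzma, a granule protease, 61.0 and 15.3 CPM (interval of the ratio -2.62 to -1.42). Ncr1 there was at -0.79. NK receptor genes in cluster 3 were lower for 18 of 23 members (median -0.31, -0.53 to -0.20, below all random lists), with Klra8 at 28 and 1 UMIs (-4.06, -9.41 to -1.46). Summed NK markers (807 and 727 CPM, -0.15), T cell markers (-0.11) and plasma cell markers (374 and 197 CPM, -0.93) were lower there too. Gzma stood at 67.7 and 35.8 CPM in the plasma-like cluster 8, so its level in cluster 3 was no higher than there. Whether free RNA or mixed barcodes, rather than the cluster 3 cells, gave the low Gzma and Klra8 counts was not tested. Higher in KO_LP in cluster 3 were Cxcl10 (56.5 and 141.5 CPM, 1.33), the ubiquitin ligase gene Siah2 (42.8 and 79.8 CPM, 0.90) and Lars2 (0.69). In the ILC3-like cluster 6 (184 and 105 cells) Csf2 had 115 and 40.5 CPM (-1.51), Ccl3, an inflammatory chemokine, 104 and 12.9 CPM (-3.01, -4.26 to -1.97, on 95 and 8 UMIs), Lilr4b 196.5 and 85.8 CPM (-1.20) and Ncr1 391 and 277 CPM (-0.50). Type 1 cytokine genes in cluster 6 were lower for 7 of 10 members (median -0.48, -0.76 to -0.22, below all random lists), a median that came to 0.043 with no cell filter and to 0.0044 when the clusters were built without the outcome lists. In cluster 6 summed ILC3 markers (5739 and 4402 CPM, -0.38), ILC2 markers (-0.51) and T cell markers (-0.14) were lower and B cell markers (1184 and 1449 CPM, 0.29) higher in KO_LP. Cxcl10 (47.2 and 162 CPM, 1.78) and Platr3 (16.5 and 68.0 CPM, 2.05) were higher in KO_LP in cluster 6. S100g, an enterocyte calcium-binding protein, had 0 UMIs in WT_LP and 52 in KO_LP there, all from 2 cells.

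The T-like cluster 4 (401 and 419 cells) also had lower granzyme transcript in the library labelled KO. Gzma stood at 279 CPM in WT_LP and 93.7 CPM in KO_LP (log2 ratio -1.57, -1.79 to -1.36), Gzmb at 346.5 and 161 CPM (-1.10, -1.28 to -0.93) and Ncr1 at 106.6 and 41.7 CPM (-1.35, -1.69 to -1.03). Over all T-like clusters Gzma had a ratio of -1.89 and Gzmb one of -0.47 (406 and 292 CPM). Gzmb was higher in KO_LP in cluster 7, which it helps to define (1122 and 1361 CPM), and in cluster 9 (125.0 and 187 CPM). In the small cluster 14 (69 and 23 cells) it was lower (421 and 7.78 CPM), and in cluster 17 (45 and 12 cells) higher (9.42 and 146 CPM). In cluster 4 summed NK markers (8027 and 6785 CPM, -0.24), ILC3 markers (-0.34), ILC2 markers (-0.85) and T cell markers (-0.11) were lower in KO_LP as well. The heat-shock genes Hspa1a (365 and 879 CPM, 1.27), Hsph1 (1.19) and Hspa1b (1.03) were higher in KO_LP. In cells with little heat-shock RNA, which were chosen by these genes, Hspa1a was at -0.23 and Hspa1b at -0.46. TCF1 program genes had a median of 0.24 (9 of 14 higher, percentile 99.9), and their leading members were low-count genes, Myb (1 and 19 UMIs) and, the other way, Ccr7 (13 and 1 UMIs, from 2 cells and 1 cell).

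Markers of other cell types and RNA quality differed between the libraries as well. In clusters 1 and 2, NK markers summed to 4596 CPM in WT_LP and 3788 CPM in KO_LP (log2 ratio -0.28, -0.30 to -0.25), ILC1 markers to 8789 and 8080 (-0.12), ILC2 markers to 273.6 and 244.5 (-0.16) and ILC3 markers to 1386 and 1374. Plasma cell markers summed to 399 and 204 CPM, T cell markers to 1865 and 1886, B cell markers to 251 and 270.3, myeloid markers to 235.5 and 200.8, stromal markers to 91.1 and 81.1, epithelial markers to 27.2 and 20.6, proliferation markers to 24.4 and 20.7, mast cell markers to 6.33 and 5.63 and erythroid markers to 3.97 and 12.0. Summed heat-shock RNA over all kept cells was 1522 CPM in WT_LP and 2153 CPM in KO_LP, and the median mitochondrial share was 2.36% and 2.59%. The X-inactivation transcript Xist had 1015 and 950.3 CPM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1 UMI or none in each library.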

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

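No test was run on the differences in this part, which were found by looking through all genes after the data were seen. Genes are listed when their CPM differed at least 1.5 times between the libraries in opposite directions in 2 cell groups, with both counting intervals away from 0 on their own side. Cxcl2, a neutrophil chemokine, had a higher CPM in the library labelled KO in clusters 1 and 2 (30.9 and 79.0 CPM) and a lower one in cluster 0 (127 and 50.4 CPM), and the log2 ratios lay 2.69 apart. Ccr2, a chemokine receptor, went the other way, with 157 CPM in WT_LP and 98.7 CPM in KO_LP in clusters 1 and 2 against 30.5 and 52.3 CPM in cluster 0, a difference of -1.45 between the ratios. Tyrobp, the signalling adaptor of many NK receptors, had 722 and 477 CPM in clusters 1 and 2 and 178 and 275 CPM in cluster 6, a difference of -1.23. S100a4, a calcium-binding protein of motile cells, had 62.7 and 31.3 CPM in NK-like cells and 254 and 382 CPM in cluster 6, a difference of -1.59. The differences between these ratios were not tested.

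The barcodes left out by the cell filter or as doublet calls carried a signal outside the main comparison. In KO_LP, 297 such barcodes had 11.5% of their UMIs from haemoglobin genes (80852 UMIs), against 2.62% in the 398 left-out barcodes of WT_LP (14321 UMIs). In the kept cells the haemoglobin sums were 194 UMIs in KO_LP and 126 in WT_LP.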

How the results depend on the processing

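Alternatives added after the data were seen were the 5% highest doublet scores removed, cluster 1, 2 or 5 alone, shares of cells outside cluster 0 only, and cells with little heat-shock RNA. Of 1424 log2 ratios of genes recomputed under alternatives, 1228 stayed within the counting interval of the value in the report, 169 left it and 27 reversed. A change of sign counted as reversed only where the interval of the reported value excluded 0, so values that left it can also have changed sign. With all kept cells, the tissue egress median of clusters 1 and 2 went from -0.08 to 0.27 and was not counted as reversed. For list medians these numbers were 336, 40 and 8 of 384, and for cell shares 59, 8 and 2 of 69. Ncr1 in clusters 1 and 2 stayed between -1.04 and -0.94, and Zfp683 between -0.23 and 0.32. Taking all kept cells of the library in place of a group replaces the cells themselves, so the mix of cell types enters. In clusters 1 and 2 it gave -0.073 for Gzmb and 0.30 for Tcf7, and list medians of -0.057 for granule, 0.38 for TCF1 program and -0.23 for type 1 cytokine genes. It reversed Jchain (0.57, also in NK-like cells and cluster 0), Ctla2a (0.044), Cxcl2 (-0.57), Il7r (-0.38), Ly6c2 (0.16), Klra8 (0.27, also in cluster 3), Klra9 (0.27), Rgs16 (0.55) and Oasl2 (-0.17) there. In NK-like cells it reversed Cd3g (0.045), Fasl (0.19) and Gpr55 (0.63). In cluster 0 it reversed Ccl5 (0.19), Xcl1 (0.029), Ccr2 (-0.010) and Adgrg5 (-0.14), and in clusters 3 and 4 Gzma (0.12), Siah2 (-0.094) and Ccr7 (0.38). The NK receptor median became 0.13 against clusters 1 and 2, 0 and 3, the immediate early median -0.0064 and the survival median 0.031. Cluster 1 alone gave a type 1 cytokine median of -0.22, and cluster 2 alone one of -0.37 and a reversed Il22 (0.059). In cells with little heat-shock RNA, chosen for that property, Gzmb was -1.28, Hspa1b -0.082 (in cluster 4 -0.46, with Hspa1a -0.23), the type 1 cytokine median -0.36, the immediate early median -0.053 and the NK-like egress median 0.10. With no cell filter the cluster 3 share difference was 0.605 points and the cluster 6 type 1 cytokine median 0.043. Clustering without the outcome lists gave -1.28 for Gzmb and type 1 cytokine medians of -0.24 in clusters 1 and 2 and 0.0044 in cluster 6. Each library clustered alone gave share differences of 13.5 points for clusters 1 and 2 and -11.6 points for cluster 0. Among cells outside cluster 0 the share difference was 4.38 points for clusters 1 and 2 and reversed to -0.67 points for NK-like cells, because the lower cluster 0 share raises all others. Apart from the whole-library, outside-cluster-0 and heat-shock settings, the cause was not tested. No paired analysis was possible because gene counts were analysed here for 1 tissue only, with 1 library per genotype. The depth limits ratios of genes with under about 50 UMIs in a group, such as Klra8, Rgs16 and Zfp683.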

Other observations

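Beyond the groups compared, Zfp683 was also found in the T-like cluster 7, at 15.7 CPM in WT_LP (8 UMIs, 115 cells) and 11.5 CPM in KO_LP (5 UMIs, 94 cells). Among small populations, proliferating-like cells made up 0.645% of the cells in WT_LP and 1.42% in KO_LP, plasma-like cells 1.86% and 3.10% and the Il17a-led T-like cluster 14 1.35% and 0.667%. Cxcl10, an interferon-induced chemokine gene that helps to define cluster 11, had a higher CPM in KO_LP in NK-like cells and in clusters 3 and 6.

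The tests below were chosen only after the result was seen, except those on heat-shock cells and on the mix of subclusters, whose predictions were written before their own results were seen. Gzmb in clusters 1 and 2 was lower in the library labelled KO. A loss of Gzmb UMIs evenly across the library would lower it in NK-like cells too, but its log2 ratio in the NK-like cluster 5 was 0.44 (0.35 to 0.53). In the small NK-like cluster 12, which Gzmb helps to define, it had 3277 CPM in WT_LP and 2298 CPM in KO_LP. Gzmb was also lower in KO_LP in the T-like cluster 4 (346.5 and 161 CPM) and cluster 3 (27.6 and 12.0 CPM). Cluster 6 had 18.7 and 6.48 CPM, near the low level of cluster 0 (13.6 and 10.6 CPM), and the interval of its log2 ratio held 0. Gzmb was higher in the T-like clusters 7 and 9. A loss limited to some cell groups was not tested, and cluster 5, with much Gzmb of its own, cannot test free RNA. A heat-shock response does not account for the lower Gzmb in clusters 1 and 2, since the ratio in cells with little heat-shock RNA was -1.28 (-1.45 to -1.10). A different mix of the subclusters compared accounts for only part of it. With each weighted by its share of the cells of both libraries, -0.87 (-1.02 to -0.74) was left, with Gzmb lower in 5 of 5 subclusters. The subcluster with the highest Gzmb (591 and 314 CPM) held 411 cells in WT_LP and 151 in KO_LP. A different mix within subclusters was not tested. What stays open is whether loss of Hobit, in a library where Zfp683 3′ tags were not lower, or another difference between the animals or captures may be the cause, which 1 library per genotype cannot separate.

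Ncr1 was lower in KO_LP in 6 of 6 cell groups with at least 50 CPM, and the ratio nearest 0 was -0.50 (-0.77 to -0.23) in cluster 6. A candidate explanation is the Cre driver in Ncr1 itself, or a linked difference in that gene, which predicts a lower value in every group, also where Zfp683 is near its floor. Cluster 0 had 4 Zfp683 UMIs in WT_LP (0.583 CPM, against 7.50 CPM in clusters 1 and 2) and an Ncr1 ratio of -0.71 (-0.83 to -0.59). These values cannot decide whether a lack of Zfp683 in the same cells at capture plays a part. Zfp683 was detected in only 3.85% of the WT_LP cells of clusters 1 and 2, and its 3′ tags were not lower in KO_LP. Ncr1 lies on chromosome 7 from 4337724 to 4345164 (plus strand, GRCm38). An effect of Zfp683 loss earlier in development was not tested.

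The share of cluster 0 was lower in KO_LP. Assignment of its cells to the neighbouring clusters 3 and 6 is argued against, since clusters 0, 3 and 6 together differed by -17.5 points (-19.5 to -15.5). A difference in sort gate or recovery cannot be told apart from genotype, since the labels give no gate and there is 1 library each. Shares sum to 100%, so a lower cluster 0 raises the others by itself, and among the cells outside cluster 0 the T-like share differed by 1.86 points (-0.091 to 3.83), which decides nothing. A biological explanation, a lower number of these cells in mice of the KO genotype, remains untested with 1 library each.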
